A study of Mus musculus with 15 samples.

How the data were processed

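RNA from the livers of 15 male C57BL6J mice, aged 9.5 months per the labels, was sequenced, with 1 library per animal. Per the labels' protocols, directional libraries were made from 250 ng of total RNA and read as single reads of 75 nt. Animals with diethylnitrosamine (DEN), a liver carcinogen, received 25 mg/kg at 2 weeks of age. They were then kept on a high fat diet (HFD, 60% of energy from fat) for 32 weeks, and the other animals stayed on chow. MCOPPB, a ligand of the nociceptin/orphanin FQ opioid receptor, was given intraperitoneally at 5 mg/kg, with 5 daily injections and 2 days of washout per cycle, for 3 cycles and 21 days in all. Control animals received saline. The groups were taken from the sample titles: chow saline (n = 3), chow MCOPPB (n = 5), DEN/HFD saline (n = 4) and DEN/HFD MCOPPB (n = 3). Replicate numbers were treated as labels of separate animals. Of 19 pairs of libraries that carry 1 number in 2 groups, 5 had residuals correlated above 0.1, and their mean correlation was -0.0273 beside 0.00840 for 64 other pairs.

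Per the submitters' processing notes, the tools were Trimmomatic, STAR 2.7.0e, HTSeq and DESeq2 with the GRCm38 (mm10) genome. Their roles and settings were not stated. The deposited values are variance-stabilised expression levels on a log2 scale, made by the authors, for 54281 versioned Ensembl gene IDs in 15 columns. Their lowest value, 5.49, is shared by all libraries and stands for 0 reads. Of the genes, 31133 were at this value in every library, and 11201 were above it in every library. On this scale, differences of genes with few reads are compressed toward 0. The transformation was inverted to normalized counts, used for levels and ratios. Of the inverted values under 20 reads, 15.1% to 45.1% per library were whole numbers of reads (within 0.01 read), so read counts were not recovered. A fit of recovered reads with voom, foreseen beforehand, was therefore not run. Gene names and positions came from GENCODE M21, where 54107 IDs were found, 53544 of them with the version in the file. This copy of the annotation may differ from the one the authors used.

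The inverted value that most genes with few reads share in a library was taken as 1 read. Depth estimated on this basis ranged from 9.32 M to 18.7 M assigned reads per library (median 15.0 M). Since reads were not recovered, these depths are estimates, and no counting interval is given.

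Genes were kept when their value lay at least 1 (log2) above the lowest value in at least 3 libraries, which corresponds to 22.5 normalized counts, and 11568 genes passed. The test was limma 3.58.1 in R 4.3.3: a linear model with 4 group means over all 15 libraries, contrasts, and eBayes with a mean-variance trend, with 11 residual degrees of freedom and a median of 6.34 prior degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over the 11568 genes, and a gene was called at an adjusted p under 0.05. The contrasts were MCOPPB against saline within each diet, DEN/HFD against chow within each treatment, and the difference between both MCOPPB effects. A common MCOPPB effect came from a model with diet as an additive term. No covariate was used. Errors of log2 differences are the moderated standard errors (SE) of the limma model, and errors of levels are standard deviations (SD) between libraries. The adjusted p values in the text come from limma unless another test is named, and all tests were two-sided.

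The groups, comparisons, 41 gene lists, alternatives and the rule for named genes were written before the data were examined. Of the lists, 38 had at least 5 kept members and were tested with limma's camera (preset correlation 0.01, adjusted over the 38 lists within a comparison). The same test was run with an estimated correlation between genes, and with the rotation test fry. Named genes were the 6 largest rises and 6 largest falls among called genes with non-overlapping groups. Where fewer than 10 genes were called, all called genes and those with the smallest p were named, up to 10. Added to these were up to 4 members with the smallest p of each list that passed camera or had at least 3 called members, and Oprl1, Pnoc, Cdkn1a and Cdkn2a. For the difference between MCOPPB effects, the 6 smallest p values were named. For DEN/HFD in MCOPPB mice, genes already named were used. Means of lists per library were compared by exact permutation tests, 48 in all. Correlations between effects were computed across genes, beside 100 simulated sets of unchanged groups sharing libraries.

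The scripts were tested on simulated data, with 200 changed genes per comparison and noise drawn independently for each gene. More genes were called there (178 for MCOPPB on chow) than in the study, which loosens the adjusted threshold. The shares called may therefore be higher than in the real data. With changed genes added to unchanged ones at the group sizes of the study, 71.0% of genes changed by 1 (log2) were called for MCOPPB on chow, 53.0% for MCOPPB under DEN/HFD, 58.0% for DEN/HFD in saline mice, 67.0% for DEN/HFD in MCOPPB mice and 18.0% for the difference between MCOPPB effects. For a change of 2, these shares were 100% for MCOPPB on chow and 96.0%, 92.0%, 99.0% and 77.0% for the others, in the same order.

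Other settings fixed beforehand were no filter or a stricter one (at least 2 above the lowest value), quantile normalization, centring on each library's median, robust moderation, moderation without a trend, fitting only the groups compared, array weights, the replicate number as a block, the RNA integrity number (RIN) as a covariate, and leaving out each library in turn. Chosen after seeing the data were log2 values of the normalized count plus 1 or plus 5, leaving out chow saline 2 and chow MCOPPB 4 (the libraries least correlated with the others), each library's median correlation to the others as a covariate, RIN as a covariate for the lists, the list means on leaving out each library, and a list without the members it shares with others. The rotation test fry was also read for change in either direction (its mixed test). The labels list 2 RIN values per animal. Values listed second run in the same order in both diets, so values listed first were used. DEN, HFD and the order of the library numbers go together in these samples and cannot be separated. Within each diet, the bracketed numbers in the sample titles also run in blocks by treatment. Their meaning is not stated, so treatment and this order cannot be separated either.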

Results

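Liver RNA was profiled in 15 male mice on chow or under DEN/HFD, a model of progressive fatty liver disease with a carcinogen, each with saline or with MCOPPB. There were 3 chow saline, 5 chow MCOPPB, 4 DEN/HFD saline and 3 DEN/HFD MCOPPB animals. The depth was estimated at 9.32 M to 18.7 M assigned reads per library. Per library, 13863 to 16675 genes lay above the lowest value. The 10 most abundant genes took 32.0% to 43.6% of normalized counts, with albumin (Alb) first in every library. Transcripts of the mitochondrial genome took 12.01% to 30.95%, with group means of 23.8% ± 4.95 (SD, n = 3) for chow saline, 20.1% ± 6.28 (n = 5) for chow MCOPPB, 16.6% ± 4.78 (n = 4) for DEN/HFD saline and 19.7% ± 0.896 (n = 3) for DEN/HFD MCOPPB. RIN averaged 9.23 ± 0.404 (n = 3), 9.96 ± 0.0548 (n = 5), 8.85 ± 0.342 (n = 4) and 9.00 ± 0.265 (n = 3) in the same order, so chow MCOPPB had the highest values. The first principal component held 22.8% of the variance and the second 16.9%.

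**Figure D1:**
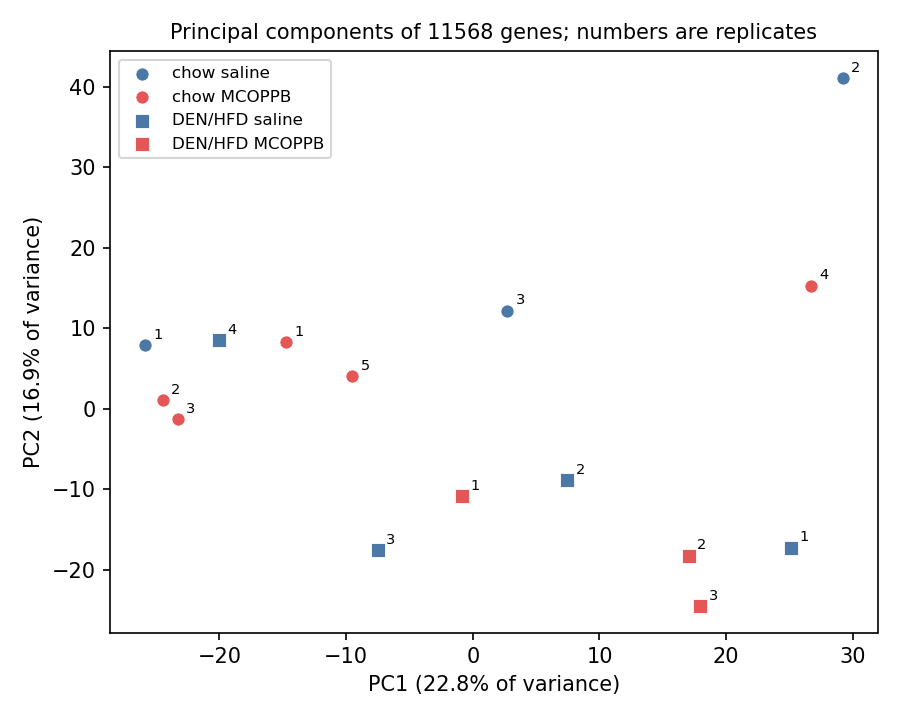
Scores of the 15 libraries on principal components 1 and 2 of 11568 genes (log2 scale), with colour for treatment, shape for diet and numbers for replicates. Component 1 holds 22.8% and component 2 holds 16.9% of the variance, and DEN/HFD saline 4 lies beside chow libraries.

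The first comparison asked what MCOPPB, named as a senolytic in the series title, changed in livers of chow mice. Genes known for female-biased liver expression rose and genes known for male-biased expression fell. Cyp2b9, a female-biased cytochrome P450, rose from 16.3 ± 15.3 normalized counts (SD, n = 3) to 3296 ± 939 (n = 5), a log2 difference of 5.50 ± 0.29 (SE, limma adjusted p = 6.97e-09). This gene (ENSMUSG00000040660.6) lies on the plus strand of chromosome 7, from 26173411 to 26210661. Mup20 (ENSMUSG00000078672.2, chromosome 4, minus strand, 62050234 to 62054158), a major urinary protein secreted by male liver, fell from 111500 ± 11750 (n = 3) to 6033 ± 2334 (n = 5) normalized counts, a log2 difference of -4.31 ± 0.42 (limma adjusted p = 2.21e-05). Hsd3b5, a male-biased steroid reductase, averaged 1698 ± 324 normalized counts with saline and 36.4 ± 47.5 with MCOPPB, a log2 difference of -4.30 ± 0.71. Elovl3, a fatty acid elongase, averaged 689 ± 153 and 43.2 ± 24.8, a log2 difference of -2.78 ± 0.26.

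In all, limma called 37 of 11568 genes for MCOPPB on chow, 18 higher and 19 lower, and 1048 genes had an unadjusted p under 0.05. Of these 37 genes, 21 belong to the sex-biased lists. The other largest rises were Cyp2a4 (3.74 ± 0.70), Cyp2c69 (2.88 ± 0.35), Cyp2b13 (2.82 ± 0.22), Cyp2c40 (2.81 ± 0.32) and Cyp2a22 (2.71 ± 0.34), all cytochromes P450. Cyp2b13 was at the lowest value in all 3 chow saline libraries and at 249 ± 121 normalized counts in chow MCOPPB. The other largest falls were the major urinary protein genes Mup19 (-4.22 ± 0.84), Mup17 (-4.19 ± 0.68), Mup11 (-3.72 ± 0.70) and Mup9 (-3.68 ± 0.73). Reads of the Mup genes, of Cyp2a4 with Cyp2a5, and of Cyp2c40 with Cyp2c69 can match more than 1 gene, so values of single members are less certain than those of the families.

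As groups, 26 of 26 female-biased genes had a positive log2 difference, with a median of 1.15. Of these, 9 were called over all genes and 23 when adjusted over the list alone (camera adjusted p = 5.28e-40, and adjusted p = 0.000589 with an estimated correlation). Of 30 male-biased genes, 29 had a negative difference, with a median of -1.57. Over all genes 12 were called, and 21 when adjusted over the list alone (camera adjusted p = 5.93e-39, and adjusted p = 0.0129 with an estimated correlation). Cyp4a12b (-2.96 ± 0.35) and Mup21 (-2.88 ± 0.36) were among the members that fell. The mean level of the female-biased list was 8.69 ± 0.30 (log2, SD, n = 5) in chow MCOPPB and 7.13 ± 0.25 (n = 3) in chow saline, with no overlap. An exact permutation test gave p = 0.0179, the smallest it can give with 5 and 3 animals, and 0.0714 when adjusted over 48 such tests. The male-biased list gave the same p for 9.54 ± 0.36 and 11.44 ± 0.11. The count of 37 genes was 13 without chow saline 3, 15 with RIN as a covariate and 23 with the replicate number as a block. Cyp2b9, Cyp2b13 and Mup20 were called in each of these fits.

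**Figure D2:**
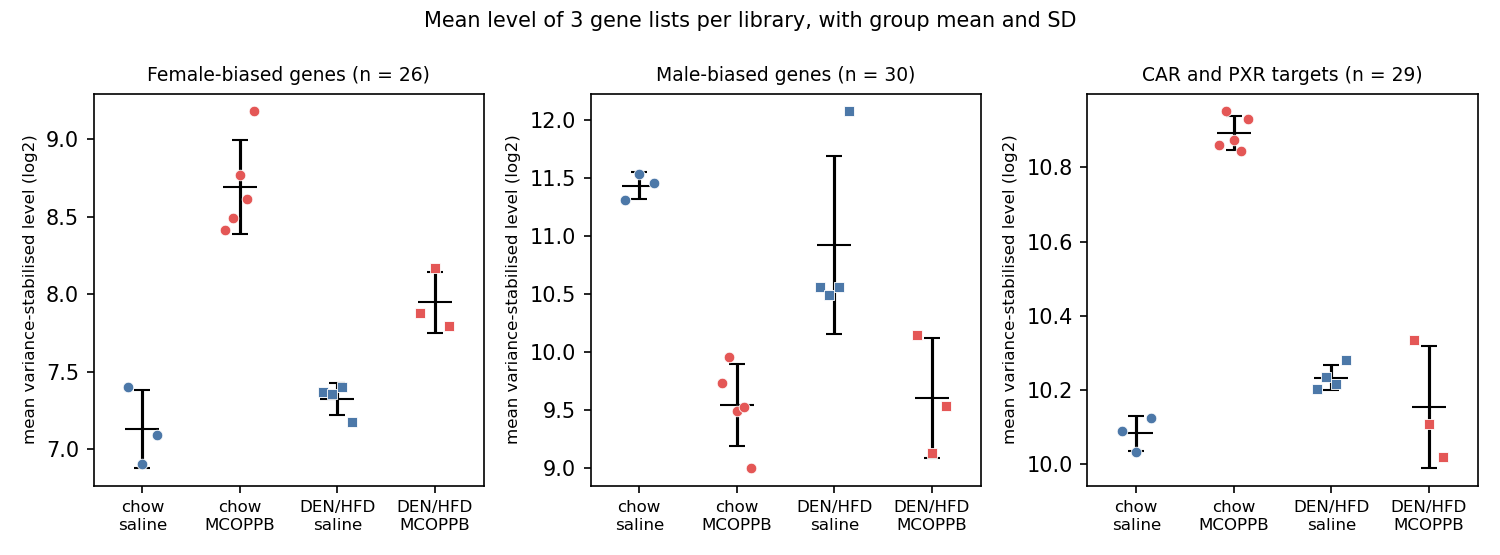
Mean variance-stabilised level (log2) of the members of 3 gene lists in each of the 15 libraries (points), with group mean and SD (bars). Chow MCOPPB averages 8.69 for female-biased genes beside 7.13 in chow saline, and 9.54 for male-biased genes beside 11.44.

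Most listed targets of the xenobiotic receptors CAR and PXR had positive differences with MCOPPB on chow. Of 29 members, 27 had a positive difference (median 0.52), 4 were called over all genes and 10 when adjusted over the list alone (camera adjusted p = 1.31e-14, and adjusted p = 0.000410 with an estimated correlation). This list shares Cyp2b9 and Cyp2b13 with the female-biased list, and its other 27 members had a median of 0.50 (camera adjusted p = 1.42e-09, a test chosen after seeing the data). Slco1a4, an organic anion uptake transporter, rose from 242 ± 57.6 to 858 ± 175 normalized counts (1.53 ± 0.20, limma adjusted p = 0.000433). Abcb1a, the drug efflux pump P-glycoprotein, rose from 11.6 ± 11.6 to 88.4 ± 8.67 (1.30 ± 0.22, limma adjusted p = 0.00943). Abcb1a was not called without chow saline 2, without chow saline 3, or with the replicate number as a block. Among other members, the chow groups overlapped for Cyp2b10 (5.30 to 64.4 normalized counts with MCOPPB, 0 to 54.8 with saline). They also overlapped for Cyp3a11 (8226 to 17100 and 7736 to 12170), but not for Por (3119 to 5101 and 1525 to 1775).

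Further lists passed camera on chow only with its preset correlation. Genes of cholesterol synthesis had 23 of 26 positive differences (median 0.63), none called over all genes and 10 when adjusted over the list alone. This gave a camera adjusted p = 6.04e-11, and adjusted p = 0.248 with an estimated correlation. Idi1 (1.24 ± 0.30), Msmo1 (1.15 ± 0.28) and Sqle (1.09 ± 0.30), enzymes of the sterol pathway, had the smallest p and were not called over all genes. Targets of PPARalpha and genes of fatty acid oxidation had 30 of 36 positive differences (median 0.30, adjusted p = 0.435 with an estimated correlation). In that list, 1 gene was called over all genes, and 5 higher and 1 lower when adjusted over the list alone. The called one was Acot3, a peroxisomal acyl-CoA thioesterase that is also on the female-biased list, at 2.24 ± 0.36. Markers of macrophages and monocytes had 17 of 24 positive differences (median 0.43, adjusted p = 0.376 with an estimated correlation), and Kupffer cell markers 12 of 13 (median 0.48, adjusted p = 0.248 with an estimated correlation). Acute phase genes had 26 of 34 positive differences (median 0.45, adjusted p = 0.248 with an estimated correlation). Chow MCOPPB 1 stood apart there, with a list mean of 11.92 (log2) beside 10.91 to 11.12 in the other chow MCOPPB and 10.60 to 10.68 in the chow saline libraries. Interferon response genes had 39 of 44 positive differences (median 0.28, adjusted p = 0.280 with an estimated correlation).

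The other 7 lists that passed camera on chow held no gene called over all genes. Positive differences prevailed in endothelial markers (21 of 24, median 0.17, camera adjusted p = 0.00146), glucocorticoid-responsive genes (22 of 26, median 0.24, camera adjusted p = 0.00418), heat shock genes (16 of 20, median 0.18, camera adjusted p = 0.00890) and pericentral hepatocyte genes (19 of 28, median 0.18, camera adjusted p = 0.0221). Negative differences prevailed in cytosolic ribosomal proteins (64 of 72, median -0.18, camera adjusted p = 0.00131), mitochondrially encoded transcripts (12 of 13, median -0.42, camera adjusted p = 0.00986) and adipose transcripts (5 of 6, median -0.63, camera adjusted p = 0.0435). When adjusted over the list alone, 1 endothelial marker was called higher and no member of the other 6 lists was called. None of the 7 passed camera once the correlation was estimated (adjusted p = 0.248 to 0.708 with an estimated correlation).

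The differences of list means were recomputed on leaving out each library compared, a check chosen after seeing the data. For 11 of the 16 lists called on chow, no single library shrank the difference by over 1.5 times. For cytosolic ribosomal proteins, -0.17 became 0.066 without chow saline 2 and -0.11 without chow MCOPPB 3, and -0.31 and -0.42 without chow MCOPPB 4 and chow saline 1. For mitochondrially encoded transcripts, -0.37 became -0.16 and -0.22 without chow saline 2 and chow MCOPPB 5, and -0.59 and -0.58 without chow MCOPPB 4 and chow saline 3. Adipose transcripts went from -0.46 to -0.26 without chow saline 3, and heat shock genes from 0.22 to 0.14 without chow MCOPPB 3. Targets of PPARalpha went from 0.39 to 0.21 without chow saline 2 and to 0.60 without chow saline 1.

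Change in either direction was tested with fry's mixed test, which 12 of the 38 lists passed on chow. They were CAR and PXR targets (adjusted p = 9.17e-12), female-biased genes (1.46e-08), male-biased genes (8.70e-06), bile acid synthesis and transport, Kupffer cell markers (0.00718), PPARalpha targets (0.0212), liver tumour and oncofetal genes (0.0237), cholesterol synthesis (0.0320), interferon response genes and macrophage markers (0.0350 each), and endothelial markers and pericentral hepatocyte genes (0.0412 each). The tumour list did not pass camera on chow (median -0.12 over 14 members, camera adjusted p = 0.483).

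Genes of bile acid synthesis and transport went both ways with MCOPPB on chow. Of 22 members, Slco1a4 was called higher and the male-biased uptake transporter Slco1a1 lower (-3.47 ± 0.69), and 4 were higher and 2 lower when adjusted over the list alone. The mixed test gave an adjusted p = 1.46e-08. Cyp7a1, the first enzyme of bile acid synthesis, was at 1.60 ± 0.48 and did not pass (limma adjusted p = 0.247). Among lists that did not pass on chow were lipogenesis (median -0.05 over 22 members, camera adjusted p = 0.905), glucose metabolism (0.16 over 24 members, camera adjusted p = 0.483), stellate cell and fibrosis markers (0.01 over 33 members, camera adjusted p = 0.905) and cell cycle genes (0.01 over 20 members, camera adjusted p = 0.368).

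Genes of senescence and of the senescence-associated secretory phenotype did not pass as a group on chow. Their 25 tested members had a median of 0.03, 15 positive and 10 negative, with none called over all genes or when adjusted over the list alone (camera adjusted p = 0.748). Targets of p53 had a median of 0.05 over 20 members (camera adjusted p = 0.965), and the BCL2 family -0.04 over 14 members (camera adjusted p = 0.563). Cdkn1a, which encodes the cell cycle inhibitor p21, averaged 24.3 ± 16.6 normalized counts (n = 3) with saline and 10.4 ± 6.10 (n = 5) with MCOPPB. Its log2 difference of -0.39 ± 0.27 did not pass (limma adjusted p = 0.713). Cdkn2a, which encodes p16, had a mean of 2.67 ± 4.63 normalized counts with saline and 1.33 ± 1.58 with MCOPPB on chow, too low to be kept for testing. Oprl1, the gene of the receptor that MCOPPB binds, and Pnoc, the gene of its peptide ligand, were at the lowest value in all 15 libraries. Their expression was not detectable at this depth in whole liver.

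The second comparison asked what MCOPPB changed in DEN/HFD mice. Cyp17a1, a steroid hydroxylase with female-biased liver expression, rose from 200 ± 60.9 normalized counts (SD, n = 4) to 800 ± 219 (n = 3), a log2 difference of 1.64 ± 0.26. Inmt, an amine N-methyltransferase, fell from 4543 ± 1719 to 1278 ± 247 (-1.71 ± 0.27), and Usp2, a ubiquitin protease with rhythmic liver expression, fell from 383 ± 133 to 55.3 ± 9.51 (-1.82 ± 0.29). Each had a limma adjusted p = 0.0312. Cyp17a1 (ENSMUSG00000003555.8) lies on chromosome 19 from 46667165 to 46673172, minus strand. Inmt (ENSMUSG00000003477.5) lies on chromosome 6 from 55170626 to 55175043, minus strand, and Usp2 (ENSMUSG00000032010.15) on chromosome 9 from 44067021 to 44095627, plus strand. These were the only genes of 11568 that limma called, while 548 had an unadjusted p under 0.05. The next smallest p values belonged to 9030619P08Rik (1.18 ± 0.21), Chka (1.33 ± 0.25), Mcm10 (-1.25 ± 0.24), Cyp2b9 (1.57 ± 0.31), Cyp4a12b (-1.84 ± 0.36), Gm43302 (1.61 ± 0.32) and Sqle (1.502 ± 0.309), none of which passed. No gene was called on leaving out any 1 of the 7 libraries compared or chow saline 3, after quantile normalization or with the replicate number as a block, and 6 genes were called without chow saline 2. With no filter 6 genes were called, and 8 when fitting only the groups compared or with array weights.

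**Figure D3:**
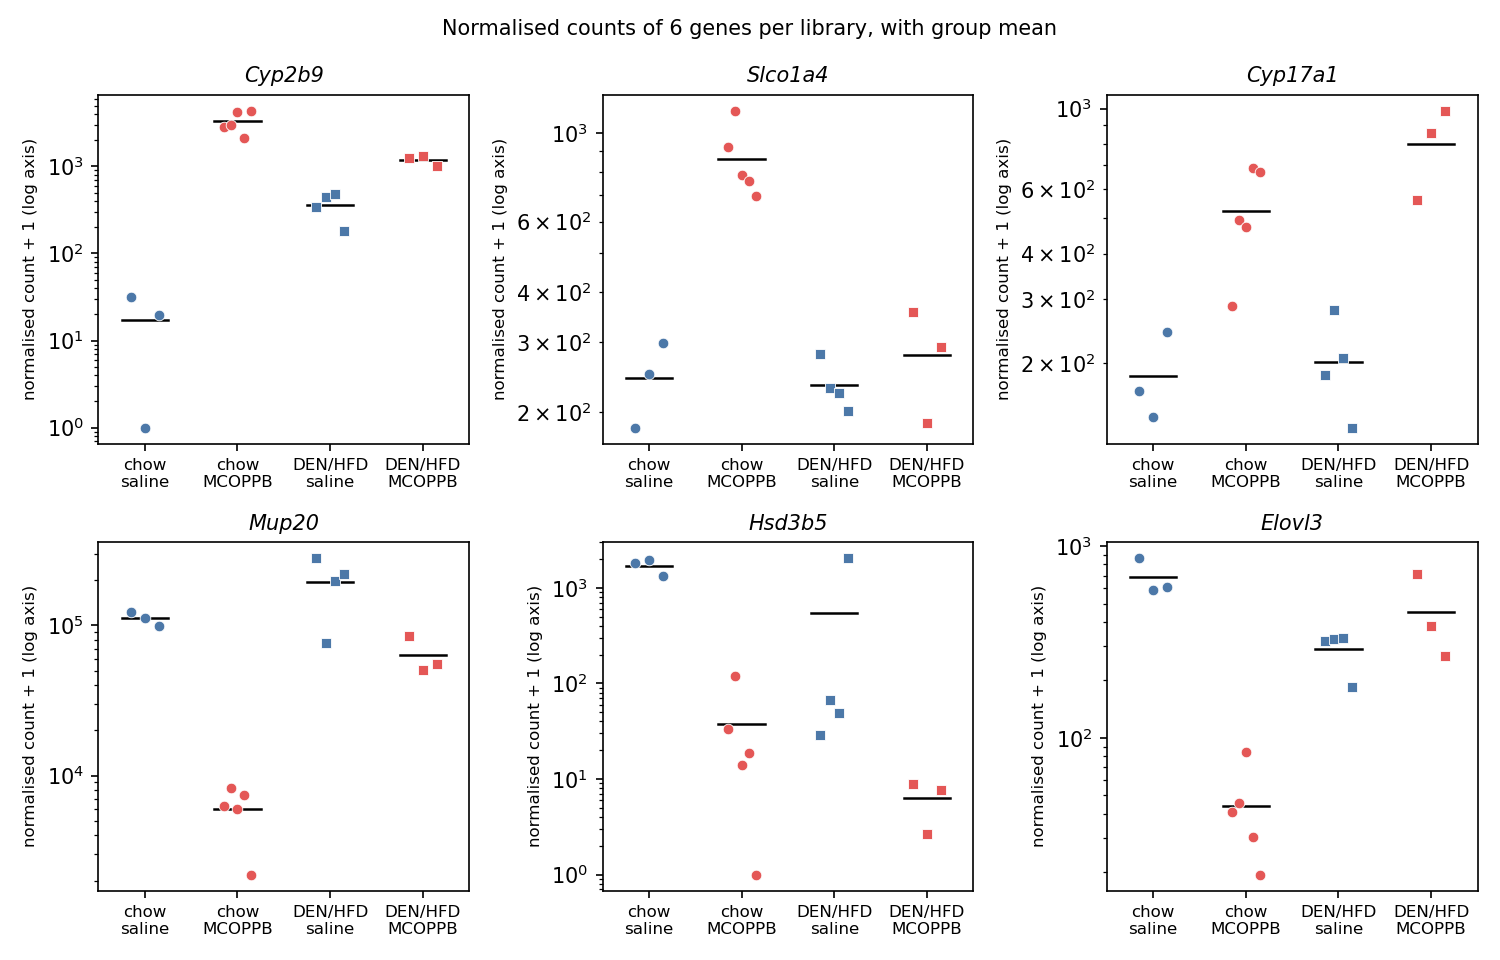
Normalized counts plus 1 (log axis) of 6 genes in each of the 15 libraries (points), with the group mean (line). Cyp2b9 averages 16.3 in chow saline, 3296 in chow MCOPPB, 363 in DEN/HFD saline and 1190 in DEN/HFD MCOPPB.

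Sex-biased genes and clock genes had mostly 1 direction with MCOPPB under DEN/HFD, and no list passed once the correlation was estimated. Of 30 male-biased genes, 29 had a negative difference (median -1.03). None was called over all genes and 18 were when adjusted over the list alone (camera adjusted p = 1.01e-25, and adjusted p = 0.0524 with an estimated correlation). Of 26 female-biased genes, 25 had a positive difference (median 0.53), 1 was called over all genes and 6 when adjusted over the list alone (camera adjusted p = 1.49e-14, and adjusted p = 0.0524 with an estimated correlation). Of 22 circadian clock genes, 18 had a negative difference (median -0.43), 1 was called over all genes and 5 when adjusted over the list alone (camera adjusted p = 5.25e-09, and adjusted p = 0.0524 with an estimated correlation). The called one was Usp2. The clock regulators Dbp (-1.71 ± 0.46), Per3 (-1.38 ± 0.34) and Tef (-0.91 ± 0.27) did not pass over all genes. Cholesterol synthesis had 22 of 26 positive differences (median 0.32, adjusted p = 0.402 with an estimated correlation).

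**Figure D4:**
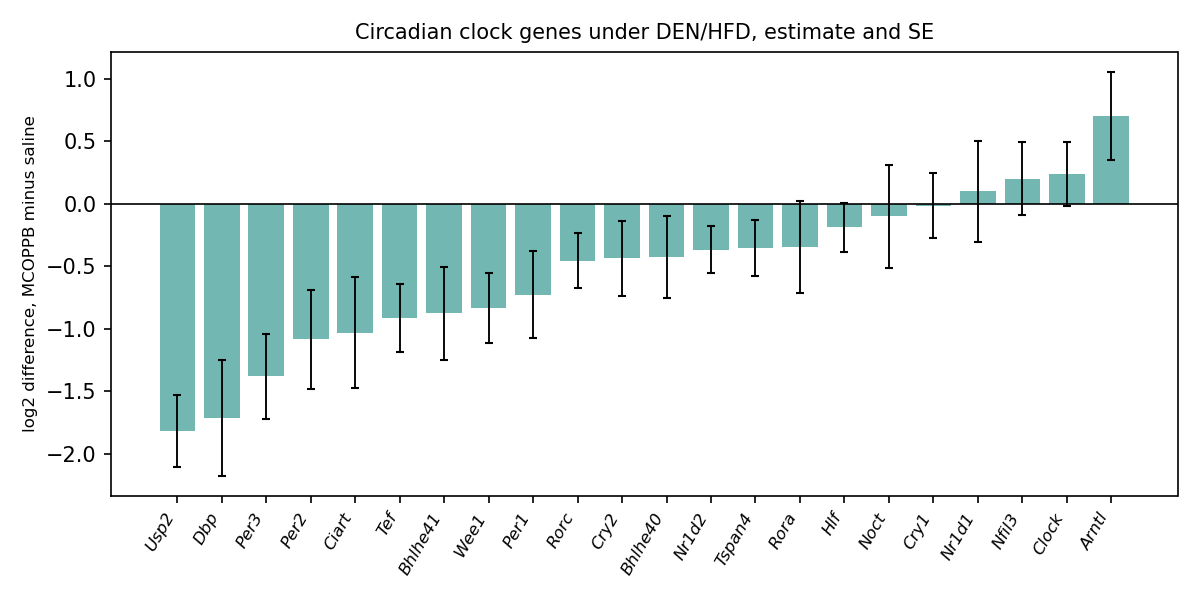
Log2 difference between MCOPPB and saline under DEN/HFD (bars) with its SE (error bars) for 22 circadian clock genes. Usp2 (-1.82) is the called member, and 18 of 22 genes are below 0.

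Under DEN/HFD too, senescence genes had no common direction with MCOPPB (25 members, median -0.08, camera adjusted p = 0.964), and none was called over all genes or when adjusted over the list alone. Cdkn1a averaged 46.6 ± 29.2 normalized counts (n = 4) with saline and 126 ± 64.3 (n = 3) with MCOPPB, a log2 difference of 0.80 ± 0.28 that did not pass (limma adjusted p = 0.836). The p53 targets had 16 of 20 positive differences (median 0.09, camera adjusted p = 0.0391, and adjusted p = 0.373 with an estimated correlation). Markers of stellate cells and fibrosis had 26 of 33 (median 0.14, camera adjusted p = 0.0320, and adjusted p = 0.695 with an estimated correlation). Macrophage and monocyte markers had 17 of 24 (median 0.16, camera adjusted p = 0.0289, and adjusted p = 0.695 with an estimated correlation). Positive differences also prevailed in interferon response genes (34 of 44, median 0.22, camera adjusted p = 0.000434), NRF2 targets (21 of 28, median 0.14, camera adjusted p = 0.0297), liver tumour and oncofetal genes (12 of 14, median 0.25, camera adjusted p = 0.0391) and the unfolded protein and integrated stress response (19 of 27, median 0.13, camera adjusted p = 0.0391). Negative differences prevailed in hepatocyte identity genes (23 of 30, median -0.16, camera adjusted p = 0.0297) and red blood cell transcripts (6 of 6, median -0.43, camera adjusted p = 0.0289). These 6 lists held no gene called over all genes and had an adjusted p = 0.668 to 0.695 with an estimated correlation. In place of 13 lists, 6 passed camera without DEN/HFD saline 4 and 8 without DEN/HFD MCOPPB 3.

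For 4 of these 13 lists, no single library shrank the difference of their means by over 1.5 times: male-biased genes, female-biased genes, clock genes and cholesterol synthesis. Without DEN/HFD saline 4, macrophage and monocyte markers went from 0.16 to -0.017, stellate cell and fibrosis markers from 0.15 to -0.0020, NRF2 targets from 0.21 to 0.037, interferon response genes from 0.18 to 0.085, liver tumour and oncofetal genes from 0.20 to 0.070 and hepatocyte identity genes from -0.19 to -0.091. Red blood cell transcripts went from -0.49 to -0.14 without DEN/HFD saline 3 and to -0.79 without DEN/HFD saline 4, and interferon response genes to 0.11 without DEN/HFD saline 3. Without DEN/HFD MCOPPB 2, p53 targets went from 0.14 to 0.083, the unfolded protein and integrated stress response from 0.14 to 0.092 and macrophage markers to 0.091. Without DEN/HFD MCOPPB 3, hepatocyte identity genes went to -0.11, tumour genes to 0.12, macrophage markers to 0.10 and stellate cell markers to 0.074, the last also to 0.098 without DEN/HFD saline 2. Larger differences came without DEN/HFD saline 1 (macrophage markers 0.30, NRF2 targets 0.32, stellate cell markers 0.23), DEN/HFD saline 2 (interferon response 0.27), DEN/HFD saline 3 (stellate cell markers 0.265) and DEN/HFD MCOPPB 1 (macrophage markers 0.29). The mixed test of fry passed for 3 of 38 lists, female-biased genes (adjusted p = 0.0179), clock genes (adjusted p = 0.0257) and male-biased genes (adjusted p = 0.0278).

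The third comparison asked what DEN/HFD changed in saline mice. Cyp2b9 rose from 16.3 ± 15.3 normalized counts (SD, n = 3) to 363 ± 137 (n = 4), with a log2 difference of 2.57 ± 0.31 (limma adjusted p = 0.00198). Gpc1, a cell surface proteoglycan, rose from 98.7 ± 54.2 to 522 ± 194 (1.77 ± 0.25, limma adjusted p = 0.0108). Jund (1.82 ± 0.29) and Jun (1.64 ± 0.28), immediate early transcription factors, rose to 1418 ± 581 and 358 ± 169 normalized counts from 325 ± 89.5 and 66.6 ± 42.6. The male-biased Cyp4a12b fell (-2.18 ± 0.36), as did Ttn, the gene of the muscle protein titin (-2.12 ± 0.35). Ttn averaged 116 ± 15.7 normalized counts in chow saline and was at the lowest value in all 4 DEN/HFD saline libraries. It was at 83.3 in chow MCOPPB 4, 12.4 in DEN/HFD MCOPPB 1 and at most 0.669 in the other MCOPPB libraries. On chow, limma also called Ttn lower with MCOPPB (-1.69 ± 0.33, limma adjusted p = 0.0330). High levels were thus particular to chow saline and chow MCOPPB 4, and the cause was not tested. These 6 genes were all that limma called, 4 higher and 2 lower, and 1268 genes had an unadjusted p under 0.05. Cyp2b9, Cyp4a12b and Ttn were also called for MCOPPB on chow, each in the same direction. Both comparisons share the chow saline libraries with the same sign, which by itself favours such an overlap. They are therefore not independent findings. Across genes, r between both effects was 0.566, beside a mean of 0.596 in simulated unchanged groups with the same sharing. Noise was drawn independently for each gene there.

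Several lists of immune markers had mostly positive differences in DEN/HFD saline livers, without passing once the correlation was estimated. B cell and plasma cell markers did not, with 7 of 10 negative (median -0.08, camera adjusted p = 0.403). Macrophage and monocyte markers had 23 of 24 positive differences (median 0.69), with none called over all genes and 13 when adjusted over the list alone (camera adjusted p = 1.17e-11, and adjusted p = 0.211 with an estimated correlation). DEN/HFD saline 4 had a list mean of 7.30 (log2), beside 7.75 to 8.24 in the other 3 DEN/HFD saline and 7.18 to 7.28 in the chow saline libraries, so the difference rests on 3 of 4 libraries. Among the markers were the complement genes C1qc (1.03 ± 0.20) and C1qa (1.04 ± 0.26), not called over all genes. All 6 MHC class II genes had positive differences (median 1.23), none called over all genes and 6 when adjusted over the list alone (camera adjusted p = 6.45e-07, and adjusted p = 0.211 with an estimated correlation). Of these, H2-Ab1 was at 1.45 ± 0.30. DEN/HFD saline 4 was lowest of its group for this list too (7.92 beside 8.48 to 9.36, with 7.52 to 7.64 in chow saline). Of 18 immediate early genes, 15 were positive (median 0.54), with 2 called over all genes and 5 when adjusted over the list alone (camera adjusted p = 5.91e-06, and adjusted p = 0.0649 with an estimated correlation). Of 28 NRF2 targets, which serve the oxidative stress response, 26 were positive (median 0.34, adjusted p = 0.245 with an estimated correlation), with none called over all genes and 4 when adjusted over the list alone. They included Nqo1 (1.12 ± 0.25) and Hmox1 (1.17 ± 0.30). For these targets DEN/HFD saline 4 lay within the chow saline range (9.41 beside 9.31 to 9.58), and the other 3 DEN/HFD saline libraries at 9.93 to 10.27. Genes of lipid droplets and PPARgamma had 18 of 21 positive differences (median 0.39, adjusted p = 0.463 with an estimated correlation), with DEN/HFD saline 4 at 8.33, within chow saline (8.16 to 8.85), and the other 3 at 9.13 to 9.55. The p53 targets had 18 of 20 (median 0.28, adjusted p = 0.148 with an estimated correlation), and the senescence list 18 of 25 (median 0.22, camera adjusted p = 0.0303, and adjusted p = 0.463 with an estimated correlation). For the senescence list too, DEN/HFD saline 4 lay within chow saline (7.47 beside 7.44 to 7.62), and the other 3 at 7.67 to 7.88. Cdkn1a did not pass, at 0.34 ± 0.28 (limma adjusted p = 0.708). Against these, mitochondrially encoded transcripts had 12 of 13 negative differences (median -0.44, adjusted p = 0.628 with an estimated correlation).

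Cell cycle genes had 19 of 20 positive differences in DEN/HFD saline livers (median 0.18, camera adjusted p = 0.00990, and adjusted p = 0.418 with an estimated correlation). Mki67, a marker of dividing cells, was at 0.75 ± 0.24 and was not called. T cell and NK cell markers had 4 of 5 positive differences (median 0.66, camera adjusted p = 0.0140, and adjusted p = 0.257 with an estimated correlation), and stellate cell and fibrosis markers 26 of 33 (median 0.19, camera adjusted p = 0.0472, and adjusted p = 0.660 with an estimated correlation). The 14 liver tumour and oncofetal genes had a median of 0.01 (camera adjusted p = 0.999). Positive differences also prevailed in interferon response genes (35 of 44, median 0.29, camera adjusted p = 0.000448), glucocorticoid-responsive genes (22 of 26, median 0.28, camera adjusted p = 0.00322), Kupffer cell markers (10 of 13, median 0.30, camera adjusted p = 0.00403), PPARalpha targets (24 of 36, median 0.15, camera adjusted p = 0.00990) and endothelial markers (16 of 24, median 0.14, camera adjusted p = 0.0299). Negative ones prevailed in male-biased genes (23 of 30, median -0.37, camera adjusted p = 0.000380), cytosolic ribosomal proteins (63 of 72, median -0.20, camera adjusted p = 0.00119), cholesterol synthesis (18 of 26, median -0.19, camera adjusted p = 0.0299) and the unfolded protein and integrated stress response (19 of 27, median -0.21, camera adjusted p = 0.0380). These 9 lists had an adjusted p = 0.300 to 0.695 with an estimated correlation.

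Many of these differences rest on 3 or fewer of the 4 DEN/HFD saline libraries. Of the 20 lists that passed camera for DEN/HFD in saline mice, DEN/HFD saline 4 lay beyond the chow saline range in the direction of the list for 10, within that range for 8 and beyond it on the other side for 2. Its mean for cell cycle genes was 6.79 (chow saline 6.79 to 6.81, the other 3 at 6.99 to 7.28), and for interferon response genes 7.36 (7.30 to 7.42, the other 3 at 7.43 to 7.91). Its mean for endothelial markers was 7.64 (7.54 to 7.66, the other 3 at 7.80 to 7.82). For stellate cell and fibrosis markers it was at 7.02, below chow saline (7.20 to 7.47), and DEN/HFD saline 2 was at 7.32, so 2 of 4 libraries lay above chow saline. For male-biased genes it was at 12.08, above chow saline (11.32 to 11.54), while the other 3 were at 10.49 to 10.57. For PPARalpha targets and cytosolic ribosomal proteins all 4 DEN/HFD saline libraries lay within the chow saline range. For cholesterol synthesis DEN/HFD saline 4 was at 9.09 and the other 3 within that range (9.42 to 9.54 beside 9.36 to 9.98).

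In 10 of these 20 lists, no single library shrank the difference of their means by over 1.5 times. Without chow saline 2, cytosolic ribosomal proteins went from -0.17 to 0.064, PPARalpha targets from 0.19 to 0.012, lipid droplet genes from 0.50 to 0.27, mitochondrially encoded transcripts from -0.45 to -0.24, stellate cell markers from 0.16 to 0.10 and cholesterol synthesis from -0.20 to -0.30. Without chow saline 3, cholesterol synthesis went to 0.0053, the unfolded protein and integrated stress response from -0.16 to -0.11 and stellate cell markers to 0.24. Without chow saline 1, ribosomal proteins went to -0.42, PPARalpha targets to 0.40 and cholesterol synthesis to -0.30. Without DEN/HFD saline 1, cell cycle genes went from 0.24 to 0.16, the senescence list from 0.17 to 0.11, stellate cell markers to 0.074 and ribosomal proteins to -0.32. Without DEN/HFD saline 2, interferon response genes went from 0.26 to 0.17, and without DEN/HFD saline 3 PPARalpha targets went to 0.11, ribosomal proteins to -0.11 and stellate cell markers to 0.040. Without DEN/HFD saline 4, cholesterol synthesis went to -0.10, ribosomal proteins to -0.080, lipid droplet genes to 0.76, stellate cell markers to 0.31 and male-biased genes from -0.51 to -0.90. The mixed test of fry passed for 6 of 38 lists: immediate early genes (adjusted p = 0.000469), macrophage markers and CAR and PXR targets (0.0106 each), female-biased genes (0.0139), the senescence list (0.0201) and Kupffer cell markers (0.0291).

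The count of 6 genes for DEN/HFD in saline mice moved with single libraries. It was 52, with all 6 among them, without DEN/HFD saline 4. It was 3 without DEN/HFD saline 1, 2 without chow saline 1 or chow MCOPPB 1, and 1 without chow saline 2, chow saline 3 or DEN/HFD saline 3. It was also 1 with RIN as a covariate and 3 with array weights.

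The same diet comparison in MCOPPB mice gave 66 called genes, 26 higher and 40 lower, and 1427 with an unadjusted p under 0.05. Genes that MCOPPB had raised on chow were lower in DEN/HFD MCOPPB than in chow MCOPPB livers, among them Cyp2b9 (-1.37 ± 0.29), Cyp2c40 (-3.38 ± 0.32), Cyp2c69 (-2.89 ± 0.35) and Slco1a4 (-1.40 ± 0.20). Elovl3 (2.18 ± 0.26) and Mup20 (3.47 ± 0.42) were higher. Of 18 genes higher with MCOPPB on chow, 11 were among the 40 lower here, and of the 19 lower with MCOPPB on chow, 3 were among the 26 higher here. Both comparisons share the chow MCOPPB libraries with opposite sign, which by itself favours such an overlap, and the overlap was not tested. CAR and PXR targets were lower in 25 of 29 (median -0.73), with 6 called over all genes and 14 when adjusted over the list alone (adjusted p = 0.000670 with an estimated correlation). Clock genes were lower in 17 of 22 (median -0.68), with 5 called over all genes and 13 when adjusted over the list alone (adjusted p = 0.0441 with an estimated correlation). The p53 targets were higher in 19 of 20 (median 0.41), with 1 called over all genes and 5 when adjusted over the list alone (adjusted p = 0.00956 with an estimated correlation). The called p53 target was Cdkn1a, at 126 ± 64.3 normalized counts (n = 3) beside 10.4 ± 6.10 (n = 5) in chow MCOPPB (1.53 ± 0.27, limma adjusted p = 0.0152). The count of 66 was 18, 28 and 27 without DEN/HFD MCOPPB 3, 2 and 1, 36, 42 and 34 without chow MCOPPB 1, 3 and 5, and 157 without DEN/HFD saline 4. No gene was called with RIN as a covariate, and 16 with the replicate number as a block, 285 with array weights and 135 when fitting only the groups compared.

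Of the 18 lists that passed camera for DEN/HFD in MCOPPB mice, the other 15 had an adjusted p = 0.0872 to 0.866 with an estimated correlation. Median differences were positive for lipid droplets and PPARgamma (0.69), NRF2 targets (0.51), macrophage and monocyte markers (0.45), MHC class II (1.10), stellate cell and fibrosis markers (0.34), immediate early genes (0.23), cell cycle genes (0.37), liver tumour and oncofetal genes (0.26) and nuclear genes of oxidative phosphorylation (0.22). They were negative for female-biased genes (-0.55), cholesterol synthesis (-0.41), red blood cell transcripts (-1.14), lipogenesis (-0.34), bile acid synthesis and transport (-0.27) and acute phase genes (-0.28). In 14 of the 18 lists, no single library shrank the difference of their means by over 1.5 times. Acute phase genes went from -0.37 to -0.19 and oxidative phosphorylation from 0.17 to 0.094 without chow MCOPPB 1, the latter to 0.30 without chow MCOPPB 4. Cholesterol synthesis went from -0.37 to -0.23 without chow MCOPPB 3, and lipogenesis from -0.35 to -0.19 and -0.53 without DEN/HFD MCOPPB 2 and 3. The mixed test of fry passed for 20 of 38 lists, 11 of them among those that passed camera. The others were senescence (adjusted p = 0.000178), the BCL2 family, PPARalpha targets, male-biased genes, Kupffer cell markers, periportal and pericentral hepatocyte genes, glucocorticoid-responsive genes and the unfolded protein and integrated stress response.

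The response to MCOPPB was then tested for a difference between diets. It was weaker under DEN/HFD for Cyp2b9, with a difference between both log2 effects of -3.93 ± 0.42 (limma adjusted p = 0.000459), Cyp2b13 (-1.93 ± 0.32) and Cyp2c40 (-2.74 ± 0.46). Elovl3, which fell on chow, averaged 289 ± 70.9 normalized counts in DEN/HFD saline and 453 ± 230 in DEN/HFD MCOPPB, and the effects differed by 3.24 ± 0.37 (limma adjusted p = 0.000535). They also differed for the predicted gene Gm43302 (2.56 ± 0.44) and for Dclre1a, a DNA crosslink repair nuclease (-1.97 ± 0.34). In all, limma called 8 genes, 3 higher and 5 lower, and 683 had an unadjusted p under 0.05. CAR and PXR targets responded less under DEN/HFD (25 of 29 negative, median -0.76, adjusted p = 0.000563 with an estimated correlation), with 2 called over all genes and 8 when adjusted over the list alone. Female-biased genes had 22 of 26 negative differences (median -0.72, adjusted p = 0.0931 with an estimated correlation), with 3 called over all genes and 7 when adjusted over the list alone. Male-biased genes had 22 of 30 positive differences (median 0.39, adjusted p = 0.514 with an estimated correlation). Clock genes had 17 of 22 negative differences (median -0.76, adjusted p = 0.155 with an estimated correlation). The mixed test of fry passed for CAR and PXR targets (adjusted p = 9.20e-09), female-biased genes (adjusted p = 8.11e-06) and clock genes (adjusted p = 0.00880), 3 of 38 lists. The count of 8 was 2 without chow saline 1, chow saline 3, DEN/HFD MCOPPB 2, DEN/HFD MCOPPB 3 or DEN/HFD saline 2, and 3 without chow MCOPPB 2, chow MCOPPB 5 or DEN/HFD MCOPPB 1. It was 4 without DEN/HFD saline 1 or DEN/HFD saline 4, 5 without chow MCOPPB 3 or chow saline 2, 2 with no filter or with the replicate number as a block, and 3 with RIN as a covariate.

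A model with 1 common MCOPPB effect for both diets called 43 genes, 16 higher and 27 lower. Sterol synthesis genes passed here: Sqle at 1.29 ± 0.21 (limma adjusted p = 0.00683) and Idi1 at 1.06 ± 0.21 (limma adjusted p = 0.0335). Cyp17a1 rose by 1.39 ± 0.18 (limma adjusted p = 0.00170), and Cyp4a12b had a log2 difference of -2.43 ± 0.28 (limma adjusted p = 0.000647). The count of 43 was 25 without chow saline 2, 26 without DEN/HFD MCOPPB 3 and 25 with no filter. Of the 37 genes called for MCOPPB on chow, 31 had the same sign under DEN/HFD, and 17 of these an unadjusted p under 0.05. Their median effect, signed by its direction on chow, was 0.67 under DEN/HFD beside 2.36 on chow. These genes were chosen by their effect on chow, which favours a larger value there. Both medians therefore do not measure how much weaker the response was under DEN/HFD. For the value under DEN/HFD alone, an exact permutation test over the 35 splits of the DEN/HFD animals gave p = 0.0286, the smallest it can give.

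Across all 11568 genes, the MCOPPB effects on chow and under DEN/HFD were correlated with Pearson's r = 0.148 and Spearman's rho = -0.0318 (permutation p = 0.309 for r over 1960 arrangements of the labels). Genes are not independent replicates. To see whether MCOPPB moved genes back toward chow levels, its effect under DEN/HFD was set against the effect of DEN/HFD in saline mice, and r was -0.139. The DEN/HFD saline libraries enter both effects with opposite sign, and simulated unchanged groups with the same sharing gave a mean r of -0.427 (-0.465 to -0.386). Noise was drawn independently for each gene there, so this range leaves out variation that genes of a library share. An observed r outside it therefore does not show an effect. With the 4 DEN/HFD saline libraries split so that no library was shared, the mean r over 6 splits was 0.0853 (-0.103 to 0.288). Without DEN/HFD MCOPPB 1 r was -0.0546, without DEN/HFD saline 1 it was -0.256, and without DEN/HFD saline 4 it was -0.239.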

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

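The tests of shared reads between paralogs, of the clock genes and of DEN/HFD saline 4 were chosen after the results were seen, as were the fits of the lists with RIN and with library similarity as a covariate. The other tests here were written before their results were seen.

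Among groups of 4 or 5 animals, 15 of 132 comparisons of 1 library with the rest of its group stood apart by Dixon's test of its gap to the nearest other library, where chance gives about 1 in 20. DEN/HFD saline 4 accounted for 6 of them. On the log2 scale it was at 8.05 for Elovl3 (others 8.66 to 8.69), 11.07 for Hsd3b5 (6.60 to 7.15) and 12.82 for Inmt (11.84 to 11.92). Its list means were 10.03 for bile acid synthesis and transport (9.68 to 9.73), 12.08 for male-biased genes (10.49 to 10.57, with 11.32 to 11.54 in chow saline) and 7.64 for endothelial markers (7.80 to 7.82). Chow MCOPPB 4 was at 7.33 for Ttn (5.49 to 5.67), at a mean of 11.05 for cytosolic ribosomal proteins (10.23 to 10.43) and at 30.95% mitochondrial transcripts (14.9% to 19.1%). Chow MCOPPB 1 was at 5.49 for Cdkn1a (6.16 to 6.32) and at a mean of 11.92 for acute phase genes (10.91 to 11.12). Chow MCOPPB 5 was at 9.53 for Jund (8.56 to 8.76) and 11.15 for Mup20 (12.57 to 13.03). Chow MCOPPB 2 had a mean of 13.85 for hepatocyte identity genes (13.53 to 13.61), and DEN/HFD saline 3 was at 6.63 for Gm43302, where its group was otherwise at the lowest value.

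The MCOPPB effect differed between diets by limma's test of the difference for 8 genes. The log2 differences between both effects were -3.93 for Cyp2b9, 3.24 for Elovl3, -1.93 for Cyp2b13, -2.74 for Cyp2c40, 2.56 for Gm43302, -1.97 for Dclre1a, 1.47 for Dtx4 and -2.25 for Usp2. By camera, 13 lists differed, with median differences of -0.76 for CAR and PXR targets, -0.72 for female-biased genes, 0.39 for male-biased genes, -0.76 for clock genes, -0.32 for PPARalpha targets, -0.33 for acute phase genes, -0.33 for Kupffer cell markers, -0.17 for endothelial markers, -0.25 for hepatocyte identity, 0.24 for the unfolded protein response, 0.52 for mitochondrially encoded transcripts, 0.21 for cytosolic ribosomal proteins and -1.18 for red blood cell transcripts. With an estimated correlation, CAR and PXR targets passed (adjusted p = 0.000563) and the other 12 did not (adjusted p = 0.0931 to 0.761 with an estimated correlation).

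Female-biased genes were higher and male-biased genes lower with MCOPPB on chow. Female animals among the chow MCOPPB mice are argued against, since the means of their Y-linked genes lay at least 2.40 (log2) above the lowest value and Xist at most 0.23. Reads shared between paralogs are argued against as the whole cause by the 27 members outside the Cyp, Mup and similar families, whose median in the direction of their list was 0.99 (quartiles 0.59 to 1.36), with 26 of 27 in that direction. RNA integrity was higher in chow MCOPPB. With RIN as a covariate the median over 56 members was 1.64 (lower quartile 0.94) beside 1.34 without it, so the shift did not shrink. Called members went from 21 to 10 as the median SE rose from 0.34 to 0.49, and 21 were called with library similarity as a covariate. RIN ran from 9.9 to 10 in chow MCOPPB and from 9 to 9.7 in chow saline, so this fit cannot fully separate RNA integrity from treatment. An effect of MCOPPB on sex-biased liver expression stays open as a hypothesis. So do RNA integrity, differences in housing or handling and other structure among the chow libraries, and no test here decides between them.

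Clock genes were lower with MCOPPB under DEN/HFD in 18 of 22, without passing once the correlation was estimated (adjusted p = 0.0524 with an estimated correlation). A single library is argued against as the cause, since the median lay between -0.56 and -0.29 on leaving out each of the 7 libraries, and the value nearest 0, -0.288 without DEN/HFD saline 4, stayed beyond 0.5 times the median with all libraries (-0.215). Collection of the groups at another time of day may account for it, though the values for this are weak. Arntl (0.70 ± 0.35), Clock (0.24 ± 0.26), Npas2 (1.04) and Nfil3 (0.20 ± 0.29), which peak in the opposite phase, had a median difference of 0.47. Npas2 was at the lowest value in saline mice and too low to be kept for testing. Arntl, Clock and Nfil3 did not pass (limma adjusted p = 0.9998 each), and both groups overlapped for them. The labels give no collection times, so another time of collection stays open beside an effect of MCOPPB on the clock, which was not tested separately.

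DEN/HFD saline 4 stood apart from the other DEN/HFD saline mice, and 52 genes in place of 6 were called for DEN/HFD in saline mice without it. A low-quality library is argued against by a median Spearman correlation of 0.925 to the other 14 libraries, rank 14 of 15 from the lowest. On a scale from 0 (chow saline) to 1 (the other DEN/HFD saline mice), over 200 genes chosen without it, it was at 0.187, beside 0.25 to 0.37 for chow saline and 0.71 to 0.89 for DEN/HFD saline libraries. Of the 52 genes, however, 25 lay beyond the chow range toward DEN/HFD, 19 within it and 8 beyond it on the other side. A chow mouse under a DEN/HFD label and a weak response of this mouse to DEN/HFD therefore cannot be told apart.

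Other splits of the same libraries into groups of the same sizes were tested for each count. The numbers of splits include the real one. For MCOPPB on chow, 2 of 56 splits reached 37 genes (highest other 932), a share under 0.05. Since 1 split across the treatments called far more genes than treatment did, this test cannot exclude a grouping by other structure. The split with 932 genes sets chow MCOPPB 4, chow saline 2 and chow saline 3 against the other chow libraries, which points to a structure of the samples besides treatment. For MCOPPB under DEN/HFD, 1 of 35 splits reached 3 genes (highest other 1), also a share under 0.05. No gene was called there on leaving out any 1 library compared, so this margin is narrow. For DEN/HFD in MCOPPB mice 1 of 56 splits reached 66 genes (highest other 2), which argues against chance. RIN ran from 9.9 to 10 in chow MCOPPB and from 8.7 to 9.2 in DEN/HFD MCOPPB, and no gene was called with RIN as a covariate. The splits therefore cannot tell DEN/HFD from RNA integrity here. For DEN/HFD in saline mice, 2 of 35 splits reached 6 genes (highest other 60), so chance is not excluded. The split with 60 genes places DEN/HFD saline 4 with the chow saline mice, which again points to a structure of the samples. For the difference between diets, 2 of 100 splits drawn from 1960 reached 8 genes (highest other 8), again a share under 0.05, although another split gave as many. These splits exchange MCOPPB and saline labels within each diet, which removes the MCOPPB effect itself. Their share therefore does not test whether the effects were equal in both diets. For the common MCOPPB effect 1 of 100 reached 43 (highest other 1), which argues against chance. Lists called by camera numbered 16 for MCOPPB on chow (1 of 56 splits, highest other 15, median of the others 8). For DEN/HFD in saline mice they numbered 20 (1 of 35, highest other 17, median of the others 10). Both counts exceeded every other split, but camera also passed many lists under arbitrary labels. With an estimated correlation 3 and 0 lists passed, so these counts say nothing on single lists. Chance is not excluded for the lists of MCOPPB under DEN/HFD (13 lists, 16 of 35, highest other 19, median 12). Nor is it for DEN/HFD in MCOPPB mice (18 lists, 11 of 56, highest other 24, median 10) or the difference between diets (13 lists, 35 of 100, highest other 18, median 11).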

How the results depend on the processing

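Chosen after seeing the data were the log2(count + 1) and log2(count + 5) scales, leaving out the 2 least similar libraries, library similarity as a covariate, RIN as a covariate for lists, the list means on leaving out each library, the CAR and PXR list without shared members, and all settings of the common MCOPPB effect. Over all settings, named genes kept their side of the threshold in 5953 values, which include sign changes of genes called in neither fit. They were no longer called in 220, newly called in 52 and reversed in 0, where a reversal was counted only with a call in either fit. For list medians, followed for only some of the 38 lists, these numbers were 1456, 103, 41 and 1. The reversed one was cholesterol synthesis for DEN/HFD in saline mice, at 0.0345 without chow saline 3 beside -0.185 (-0.339 to 0.0345 on leaving out 1 library; the cause was not tested). Among the lists whose medians were not followed were cytosolic ribosomal proteins, mitochondrially encoded transcripts, PPARalpha targets and stellate cell markers. As given above, leaving out 1 library changed the sign of the mean difference for ribosomal proteins and, under DEN/HFD, for stellate cell markers. The planned fit of recovered reads was not run.

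Counts are given where they moved by over 1.5 times or their balance of higher and lower (+ and -) by over 10 percentage points. For leaving out 1 library, ranges of totals and some balances are given further below. With all libraries they were 37 for MCOPPB on chow (18+, 19-), 3 for MCOPPB under DEN/HFD (1+, 2-), 6 and 66 for DEN/HFD in saline (4+, 2-) and MCOPPB mice (26+, 40-), 8 for the difference between diets (3+, 5-) and 43 for the common effect. The cause was not tested unless stated. No filter gave 6 (4+, 2-) for MCOPPB under DEN/HFD, 6 (3+, 3-) for DEN/HFD in saline mice, 2 (1+, 1-) for the difference and 25 for the common effect. A stricter filter gave 5 (4+, 1-) for DEN/HFD in saline mice and 6 (1+, 5-) for the difference. Median centring, robust moderation and no trend moved no count or balance of the 5 comparisons this far. Quantile normalization gave 0 for MCOPPB under DEN/HFD and 8 (4+, 4-) for the difference, with 15 lists (13+, 2-) in place of 16 (12+, 4-) for MCOPPB on chow and 13 (6+, 7-) in place of 13 (4+, 9-) for the difference. Fitting only the groups compared gave 8 (5+, 3-) for MCOPPB under DEN/HFD, 4 (1+, 3-) for DEN/HFD in saline mice and 135 (69+, 66-) in MCOPPB mice. Array weights gave 8 (5+, 3-), 3 and 285 for these. The replicate block gave 23 for MCOPPB on chow, 0 for MCOPPB under DEN/HFD, 16 for DEN/HFD in MCOPPB mice and 2 (1+, 1-) for the difference, with 8 lists (4+, 4-) in place of 13 (9+, 4-) for MCOPPB under DEN/HFD. RIN as a covariate gave 15 (9+, 6-) for MCOPPB on chow, 4 (2+, 2-) for MCOPPB under DEN/HFD, 1 (1+, 0-) and 0 for DEN/HFD in saline and MCOPPB mice and 3 for the difference, with 15 lists (13+, 2-) in place of 20 (15+, 5-) for DEN/HFD in saline mice and 11 in place of 18 in MCOPPB mice. The log2(count + 1) scale gave 4 (4+, 0-) for DEN/HFD in saline mice and 4 (1+, 3-) for the difference, and log2(count + 5) gave 3 (3+, 0-) and 4 (1+, 3-). Without the 2 least similar libraries, counts were 6 (4+, 2-) for MCOPPB under DEN/HFD, 14 (6+, 8-) and 111 for DEN/HFD in saline and MCOPPB mice and 8 (4+, 4-) for the difference. With library similarity they were 5 (3+, 2-), 48 (38+, 10-), 138 and 5, with 16 lists (14+, 2-) for MCOPPB on chow, 11 (6+, 5-) for MCOPPB under DEN/HFD and 13 (2+, 11-) for the difference.

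Lists called by camera numbered 16, 13, 20 (15+, 5-), 18 (10+, 8-) and 13 (4+, 9-) in this order. With an estimated correlation they were 3, 0, 0, 3 (1+, 2-) and 1 (0+, 1-), and by fry 3, 0, 2 (2+, 0-), 8 and 1 (0+, 1-). The correlation of the MCOPPB with the DEN/HFD effect (-0.139) reversed to 0.496 over the 6 genes called for DEN/HFD, and to 0.0853 with the DEN/HFD saline libraries split, which removes the sharing.

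Leaving out 1 library at a time gave 13 to 50 genes for MCOPPB on chow (lowest without chow saline 3), 0 to 6 for MCOPPB under DEN/HFD, 1 to 52 and 18 to 157 for DEN/HFD in saline and in MCOPPB mice (highest without DEN/HFD saline 4), 2 to 12 for the difference and 25 to 42 for the common effect (25 without chow saline 2, 26 without DEN/HFD MCOPPB 3). Lists ranged over 12 to 18, 6 to 16 (6 without DEN/HFD saline 4, 8 without DEN/HFD MCOPPB 3), 16 to 21, 15 to 21 and 8 to 20 (8 without DEN/HFD saline 2, 20 without DEN/HFD saline 3). Balances moved too. Genes for MCOPPB on chow were 8+, 5- without chow saline 3. Without DEN/HFD saline 4, genes for DEN/HFD in saline mice were 42+, 10-, and lists for MCOPPB under DEN/HFD were 2+, 4-. The correlation ranged from -0.256 to -0.0546. Depth limits genes near the lowest value: Oprl1 and Pnoc were at it in all 15 libraries, and Cdkn2a, above it in 7, was tested only with no filter and did not pass (limma adjusted p = 0.892 or more in the 5 comparisons).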

Other observations

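The test of growth hormone targets was written before its result was seen.

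Growth hormone acts on sex-biased liver expression, and lower signalling by it may underlie the shift of sex-biased genes with MCOPPB on chow. Its targets Igf1, Igfals, Socs2 and Cish and its receptor gene Ghr had a median log2 difference of -0.0466. Of these, 0 of 5 passed in either direction when adjusted over these genes alone. The largest difference was -0.61 ± 0.30 for Socs2. This neither argues for lower signalling nor excludes it, since a change in the timing of growth hormone pulses need not move these genes and no hormone was measured.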
